A study of Homo sapiens with 8 samples.

How the data were processed

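RNA sequencing of NCI-H82 cells was deposited as 1 table of 8 libraries, with 2 in each of 4 groups: pRB- or pRB+ (no doxycycline, or 0.5 µg/mL for 96 h) with vehicle or 32 nM AZD2811 for the last 48 h, from 100000 cells per mL and 500 ng RNA per library, per the labels' protocols. The series text calls the replicates biological, without saying how they were cultured, and p-values measure the spread between these samples. The sample titles call the inhibitor AZD1152, whose active form is AZD2811. The authors deposited FPKM, 1 value per gene and library; STAR 2.5.1b, Cufflinks 2.2.1 and the hg19 build are named in the submitters' processing notes, which give no role or order. The name of the sheet speaks of counts, but the values are not whole and were used as FPKM. The gene annotation behind them is not stated. The 28 rows whose gene names had turned into dates were left out, leaving 25337, of which 21924 matched a current gene symbol; genes keep the symbols of the table and no coordinates are given.

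Depth is not given in the table. It was estimated from the lowest values of 1523 genes with a single transcript of over 1500 nucleotides in GENCODE 29, where FPKM moves in steps of 1 fragment, taking the length less 200 nucleotides: 23400000 to 33900000 mapped fragments per library. At 1 FPKM as deposited in a gene of 1500 nucleotides, taken at full length, this gives a counting error of 14.0% to 16.9%. That covers counting only.

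The design written before the data were examined named a count model with trimmed-mean scaling, and limma on log2 values for tables of normalized values; since the table holds FPKM, limma 3.58.1 in R 4.3.3 was used (intensity trend, log2 of the value plus 1, Benjamini-Hochberg adjusted p under 0.05). Fold changes on that scale understate the change of low genes. That fallback did not say whether FPKM are rescaled. They were divided by a trimmed mean of log ratios to the geometric mean library (30% of ratios and 5% of levels trimmed at each end), with factors from 0.455 to 1.33, and this was decided when the numbers of genes passing with and without scaling had both been seen; the closing section gives both. Genes with a mean scaled FPKM of at least 1 were tested, 12013 in all, 282 of them small RNA genes. All 8 libraries entered a fit of 4 group means with 4 residual degrees of freedom, and 5 planned comparisons were taken from it.

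There were 2 comparisons added after the data had been examined, of 4 against 4 libraries in a fit with additive doxycycline and AZD2811 terms. For these, 8 additive fits (with or without a library type term, a robust spread estimate and small RNA genes) and a group-mean fit with that term had been looked at, with nearly the same scaling, before the plainest additive fit was chosen; all additive ones and the plain group-mean fit are reported. Library type was defined from the data, as RMRP above 1000 scaled FPKM in 3 libraries, and is not a group of the study.

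The 29 gene lists were fixed before the data were examined. Of these, 24 had at least 5 tested members and were tested by camera (preset correlation 0.01, then an estimated correlation) and fry. Some lists share members, so their results are not independent. BUB1 is in the G2/M, passenger complex and checkpoint lists, and AURKB in the passenger complex and checkpoint lists. Named genes followed a rule fixed at the same time: RB1 and AURKB; per comparison up to 8 genes that rose and 8 that fell most among those past the threshold with groups that do not overlap, small RNA and LOC genes skipped; and up to 4 members with the smallest p per described list. PLK1, SLC7A11 and the other examples come from those members. Some genes that meet the rule are not reported here. The alternatives fixed at the same time were median-ratio scaling, no filter, a pseudocount of 0.1, a replicate block, only the groups compared, a log2 fold change of at least 1 and each library left out; the count model alternatives were not run, since they need counts. Figures used Python 3.11.15 and matplotlib 3.10.9.

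The fits were tested on simulated data for the 12013 genes, with 5 runs of 200 changed genes each and independent noise of the size seen within groups, without the library type structure. For 2 against 2 libraries 31.0%, 78.2% and 96.1% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered. For 4 against 4 libraries these were 67.5%, 91.0% and 96.7%. The G2/M list was also shifted by -0.3 in the same noise, and camera called it in 5 of 5 runs with either correlation. Of 115 tests of the other lists, some of which share members with it, camera called 11 with the preset and 2 with the estimated correlation. Genes did not vary together in this noise. In the data the estimated correlation for 4 against 4 libraries was 0.173 in the G2/M list and 0.558 in the MYC target list. The runs therefore do not show how often either setting calls a list whose members vary together.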

Results

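RNA was sequenced from NCI-H82, an established line of small cell lung cancer, a tumour type that commonly lacks the retinoblastoma protein pRB. The cells carried an RB1 transgene that doxycycline switches on, so cells given 0.5 µg/mL doxycycline for 96 h are called pRB+ and cells without it pRB-. For the last 48 h each received 32 nM AZD2811, an inhibitor of the mitotic kinase Aurora B, or its vehicle, here called control. The 4 groups held 2 libraries each, 8 in total. The deposited values were FPKM for 25365 table rows, and 12013 genes with a mean of at least 1 scaled FPKM were tested. The steps of 1 fragment in low values placed the depth between 23400000 and 33900000 mapped fragments per library.

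RB1, the induced transgene, stood at 7.24 ± 0.596 scaled FPKM (SD, n = 4) in pRB+ libraries and at 0.891 ± 0.0694 (SD, n = 4) in pRB- libraries, an 8.12-fold difference. Its level ranged from 6.36 to 7.67 in pRB+ and from 0.801 to 0.95 in pRB- libraries, so each of the 8 libraries matched the pRB part of its label; the AZD2811 part was not checked. AURKB, which encodes Aurora B, measured 88.7 ± 4.93 (SD, n = 4) in pRB+ and 121 ± 9.55 (SD, n = 4) in pRB- libraries, 26.5% lower. The log2 difference was -0.46 ± 0.10 (SE) in control cells and -0.41 ± 0.10 (SE) under AZD2811, neither past the threshold (limma, adjusted p = 0.156 and 0.374). The highest pRB+ library, at 94.1, lay below the lowest pRB- library, at 110. AZD2811 moved AURKB by a log2 fold change of -0.11 ± 0.10 (SE) in pRB- and of -0.06 ± 0.10 (SE) in pRB+ cells, neither of which passed the test (limma, adjusted p = 0.992 and 1).

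**Figure D1:**
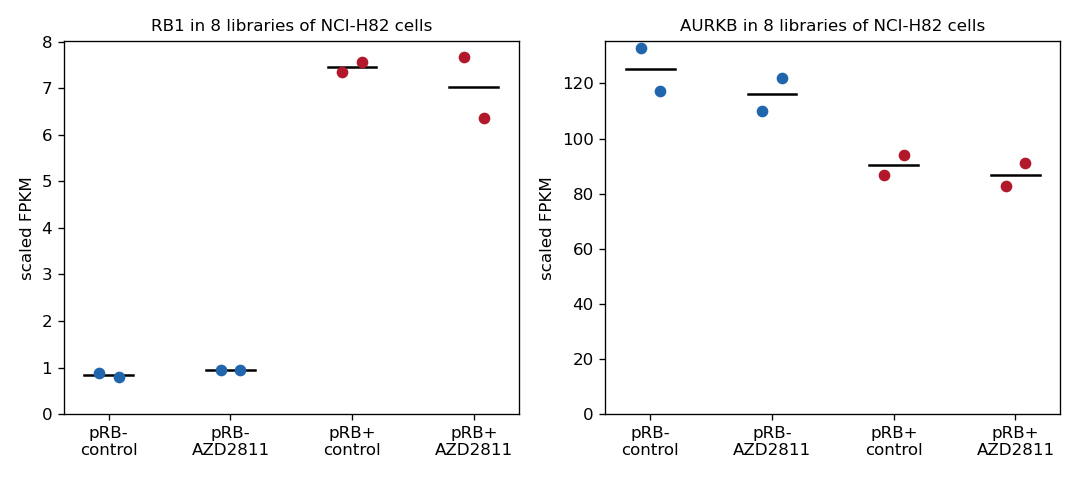
Scaled FPKM of RB1 (left) and AURKB (right) in each library; points are libraries, horizontal lines group means, and both vertical axes start at 0. RB1 lies between 6.36 and 7.67 in the 4 pRB+ libraries and between 0.801 and 0.95 in the 4 pRB- libraries.

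RNA species without poly(A) tails separated 3 libraries from the other 5. RMRP, the RNA of a ribonucleoprotein that processes ribosomal RNA, ranged from 5793 to 14002 scaled FPKM in pRB- AZD2811 replicate 1, pRB+ AZD2811 replicate 1 and pRB+ control replicate 2, and from 21.2 to 165 in the others. The RNase P RNA RPPH1 ranged from 1936 to 2383 against 5.76 to 29.6. The median of the replication-dependent histone genes, whose messages end without a poly(A) tail, ranged from 22.7 to 50.8 against 0.643 to 2.14. The first principal component, with 40.3% of the variance, separated the same libraries. The scaling factors did so too, from 0.455 to 0.771 in the 3 libraries and from 1.28 to 1.33 in the other 5. Each comparison of the control groups and of AZD2811 in pRB- cells sets groups with unequal numbers of these libraries against each other, while pRB+ and pRB- under AZD2811, and AZD2811 and control in pRB+ cells, hold equal numbers.

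**Figure D2:**
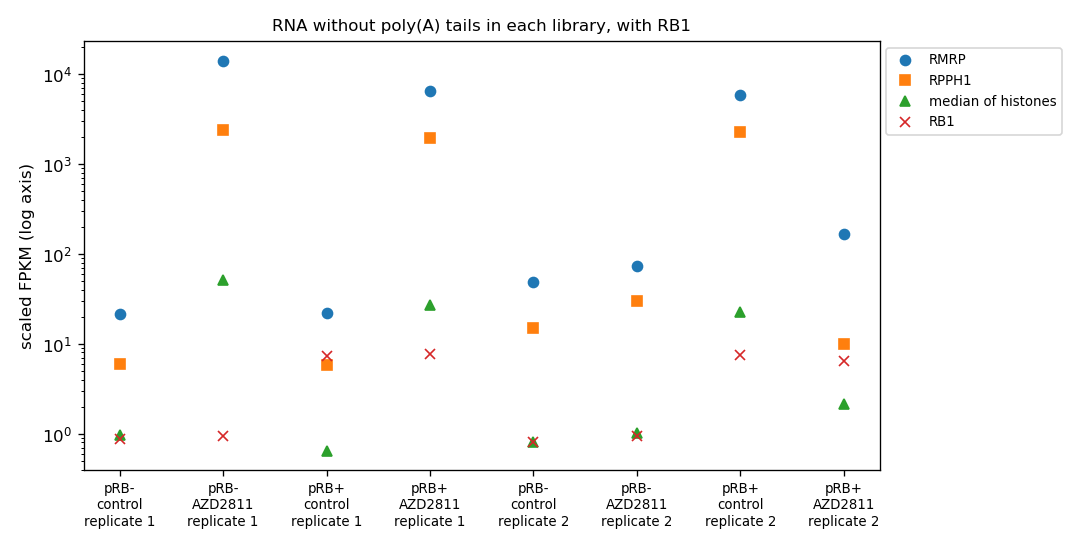
Scaled FPKM, on a log axis, of RMRP, RPPH1, RB1 and the median replication-dependent histone gene in each library. RMRP lies at 5793 or above in 3 libraries and at 165 or below in the other 5.

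The comparison of pRB+ with pRB- control cells asks what re-expressed pRB changes. RB1 rose by 2.2 ± 0.10 (log2, SE, n = 2 per group; limma, adjusted p = 0.00175), and SCRT1, a neuronal transcriptional repressor, rose by 0.79 ± 0.07 (adjusted p = 0.0376). Cell cycle genes had negative values together: the G2/M list had a median log2 fold change of -0.32 with 38 of 60 members lower when adjusted over the list alone and 0 over all genes. CCNA2 (cyclin A2) stood at -0.54 ± 0.08, KIF2C (a mitotic kinesin) at -0.78 ± 0.13 and CCNB2 (cyclin B2) at -0.49 ± 0.09, each with adjusted p = 0.144. G1/S genes, which serve DNA replication, had a median of -0.25, and 27 of 57 were lower when adjusted over the list alone and 0 over all genes, with CDT1 (origin licensing) at -0.88 ± 0.12 and ATAD2 at -0.54 ± 0.08.

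Over all genes 4 rose and 4 fell between the control groups, out of 12013 tested, and 2323 had an unadjusted p under 0.05 against 601 expected by chance. Besides RB1 and SCRT1, these were the small RNA genes SNORD67 and SNORD116-23, which rose, and MIR3940, MIR6884, MIR600 and SNORA32, which fell; each was listed at 0 in the lower group. They were named after their values were seen. Camera with its preset correlation called 9 of 24 lists, and none with an estimated correlation (adjusted p = 0.203 for the G2/M list and 0.331 for the G1/S list). The passenger complex around Aurora B had a median of -0.33, with 6 of 11 lower when adjusted over the list alone and 0 over all genes (adjusted p = 0.203 with an estimated correlation). The spindle checkpoint list had one of -0.22, with 9 of 24 lower and 1 higher when adjusted over the list alone and 0 over all genes (adjusted p = 0.203 with an estimated correlation). The SREBP target list of cholesterol and fatty acid synthesis had a median of -0.36 with 15 of 31 lower when adjusted over the list alone and 0 over all genes (adjusted p = 0.331 with an estimated correlation). Recombination and Fanconi genes had a median of -0.12 with 7 of 32 lower when adjusted over the list alone (adjusted p = 0.281 with an estimated correlation), and matrix genes one of -0.15 with 1 of 17 lower (adjusted p = 0.203 with an estimated correlation), both with 0 over all genes. The list of nucleolar MYC targets had a median of 0.21 with 2 of 39 higher when adjusted over the list alone and 0 over all genes (adjusted p = 0.55 with an estimated correlation). Replication-dependent histones, called as higher with a median of 1.77, followed the 3 libraries described above and had a median of -0.22 with a term for them. SCRT1 passed with median-ratio scaling and with a pseudocount of 0.1 (adjusted p = 0.0392 and 0.0348). It missed the threshold without the small RNA genes (adjusted p = 0.0878), with no filter (0.102), with only the groups compared (0.145), with a library type term (0.155), with FPKM as deposited (0.992) and whichever of the 8 libraries was left out (adjusted p from 0.0763 to 0.334). The count of 8 became 122 with FPKM as deposited, 17 without pRB- control replicate 1, 15 without pRB- control replicate 2, 14 without pRB+ control replicate 2, 5 without pRB- AZD2811 replicate 2, 3 without pRB+ AZD2811 replicate 2 and 1 without small RNA genes.

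In the pRB comparison under AZD2811 RB1 rose by 2.04 ± 0.10 (log2, SE, n = 2 per group; limma, adjusted p = 0.00573) and was the 1 gene that passed over all genes; 1477 had an unadjusted p under 0.05. The G2/M list had a median of -0.32 with 44 of 60 lower when adjusted over the list alone and 0 over all genes. Among them were FAM83D at -0.50 ± 0.07, the mitotic kinase gene PLK1 at -0.47 ± 0.07 and AURKA (Aurora A) at -0.38 ± 0.07, each with adjusted p = 0.374 over all genes. The G1/S list had a median of -0.18 with 12 of 57 lower, and the passenger complex one of -0.30 with 6 of 11 lower, when adjusted over the list alone (0 over all genes in both). The checkpoint list had a median of -0.18 with 7 of 24 lower when adjusted over the list alone and 0 over all genes. Camera called 8 lists with its preset correlation and none with an estimated correlation (adjusted p = 0.119 for G2/M, for the passenger complex and for the checkpoint list, and 0.471 for G1/S). The others were sterol genes (median -0.21, adjusted p = 0.471 with an estimated correlation), MYC targets (0.22, 0.473), recombination genes (-0.10, 0.377) and matrix genes (-0.093, 0.368). In these 4 lists 0 members passed over all genes (limma), and adjusted over the list alone 1 recombination gene was lower. Across the 11684 tested genes other than small RNAs and histones, the pRB effects with and without AZD2811, which share no library, correlated with Pearson r = 0.796, and 81.0% had the same sign; over all 12013 genes r was 0.258 and Spearman rho 0.744. These correlations run across genes, which are not independent replicates. The call of RB1 was lost with only the 4 libraries compared (adjusted p = 0.277) and without pRB- control replicate 1 (0.0654) or 2 (0.0648) or pRB+ control replicate 1 (0.0612) or 2 (0.0648). Without pRB- AZD2811 replicate 1 or 2 the count was 14 or 11, without pRB+ AZD2811 replicate 1 or 2 it was 5 or 8, and with FPKM as deposited it was 87.

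**Figure D3:**
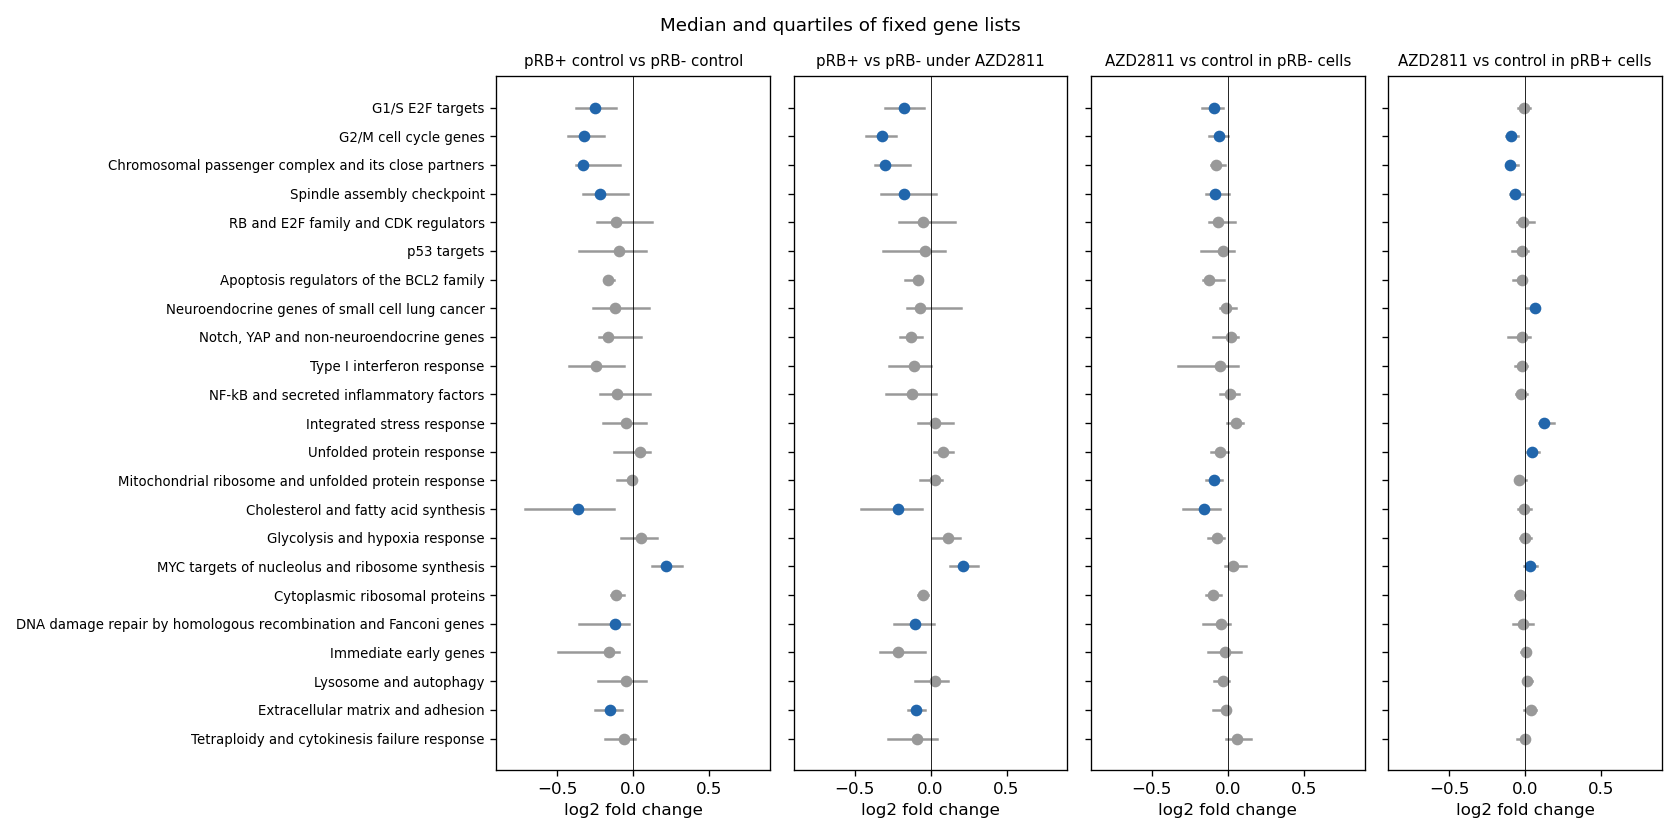
Median (points) and quartiles (lines) of log2 fold changes in the fixed lists tested, for 4 comparisons; blue points passed camera with its preset correlation, and histones are left out. G2/M genes have a median of -0.32 in both comparisons of pRB+ with pRB- and of -0.062 and -0.091 for AZD2811.

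All 4 pRB+ were then set against all 4 pRB- libraries in a fit with additive terms for doxycycline and AZD2811, a comparison added after the data had been examined. Here 643 genes rose and 698 fell among 12013 (limma, 4 libraries per arm), and 3908 had an unadjusted p under 0.05. In 2626 genes the arms did not overlap. This is 21.9% against 2.86% by chance, and 1277 of these were called. RB1 rose by 2.12 ± 0.07 on the log2 scale. Among the 8 genes with the largest falls under the rule for named genes were INSIG1 (-1.25 ± 0.25, adjusted p = 0.0311), FDFT1 (-1.22 ± 0.25) and MSMO1 (-1.17 ± 0.23), which serve sterol synthesis and its control. Also among them were the immediate early gene JUN (-1.11 ± 0.23), SAT1, RDM1 and the neurotrophin receptor gene NGFR (-0.89 ± 0.22). Under the same rule, with RB1 set aside, the 8 largest rises were those of NCOA5 (1.26 ± 0.19), YAE1D1 (1.01 ± 0.12), TAS1R3 (1.00 ± 0.18), MIR503HG (0.98 ± 0.24), TRAK2 (0.97 ± 0.13), ZNF804A, TMEM88 and MBTD1.

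In that comparison 41 of 60 G2/M genes fell over all genes and 51 when adjusted over the list alone, where 1 rose. Over all genes 0 of the 60 fell in the fit of 4 group means (39 without small RNA genes), with FPKM as deposited and in the 5 libraries low in RNA without poly(A) tails. The count was also 0 without pRB- control replicate 1 or 2, pRB- AZD2811 replicate 1, pRB+ control replicate 1 or pRB+ AZD2811 replicate 1, and 36, 33 and 38 without pRB- AZD2811 replicate 2, pRB+ control replicate 2 and pRB+ AZD2811 replicate 2. The counts over all genes for the lists below come from the additive fit of all 8 libraries, where 643 of 12013 genes rose and 698 fell. CCNA2 fell by 0.50 ± 0.05 on the log2 scale (limma, adjusted p = 0.0238), KIF2C by 0.72 ± 0.09 and AURKA by 0.38 ± 0.04. Of the G1/S genes 25 of 57 fell (34 adjusted over the list alone), among them CDT1 (-0.73 ± 0.09), ATAD2 (-0.47 ± 0.06) and ORC1 (-0.45 ± 0.06). In the passenger complex list 7 of 11 fell over all genes and 7 adjusted over the list alone, including AURKB (-0.44 ± 0.07, adjusted p = 0.0248), CDCA8 (-0.35 ± 0.04) and BUB1 (-0.35 ± 0.05). In the checkpoint list 9 of 24 fell (15 adjusted over the list alone, where 3 rose), with CDC20 at -0.46 ± 0.06. Of the RB and E2F family list 7 of 31 fell and 3 rose, RB1 included (10 and 5 adjusted over the list alone); E2F8 fell by 0.54 ± 0.06 and E2F2 by 0.46 ± 0.06. Homologous recombination and Fanconi genes held 8 of 32 that fell (11 adjusted over the list alone, where 1 rose), with RAD54L at -0.50 ± 0.06 and CHEK1 at -0.43 ± 0.06.

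Sterol genes also fell in that comparison, 10 of 31 over all genes and 19 adjusted over the list alone, with HMGCS1, an enzyme of sterol synthesis, at -0.75 ± 0.15. In the list named for nucleolar MYC targets, which also holds MAX, 11 of 39 rose (22 adjusted over the list alone). NOP58 stood at 0.58 ± 0.09 and MAX at 0.61 ± 0.10. Neuroendocrine genes went both ways: 4 of 25 rose, among them the granule protein gene CHGA (0.58 ± 0.08) and SNAP25 (0.55 ± 0.11). Another 3 fell, among them NEUROD4 (-0.73 ± 0.14), and adjusted over the list alone 4 rose and 4 fell. Of the p53 targets 6 of 28 fell, with DDB2 at -0.67 ± 0.09, and 1 rose (7 and 2 adjusted over the list alone). In the BCL2 family 0 of 11 passed on either count (limma), and in the interferon list 0 of 12 over all genes and 3 lower adjusted over the list alone. In the integrated stress list 2 of 32 rose on either count (WARS, 0.27 ± 0.06, and CBS, 0.26 ± 0.06). Matrix and adhesion genes fell in 3 of 17 (4 adjusted over the list alone), with FN1 at -0.45 ± 0.09.

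Camera called 8 lists in the 4 against 4 comparison with its preset correlation, 7 lower and 1 higher. With an estimated correlation none was called: adjusted p = 0.0946 for the G2/M, passenger complex and checkpoint lists, 0.37 for G1/S, sterol and recombination lists, 0.398 for the MYC target list and 0.326 for matrix genes. A library type term moved the estimated correlation of the G1/S list from 0.290 to 0.0491. Its adjusted p (camera) was then 0.0813, as for the G2/M, passenger complex and checkpoint lists. With the term, G1/S and G2/M lists both stood at 0.158 between the control groups and at 0.137 under AZD2811. Fry, which tests a list without setting it against other genes, called 11 lists here, 7 between the control groups and 3 under AZD2811 (adjusted p = 0.000506, 0.0133 and 0.0156 for the G2/M list). In the AZD2811 comparisons and the interaction it called 0. Without regard to direction it called 20, 15 and 10, and again 0. The count of 1341 genes depended on the fit and on single libraries. The same difference in the fit of 4 group means passed 4 genes (3410 with an unadjusted p under 0.05; AURKB adjusted p = 0.0516). Without small RNA genes that fit passed 1165, of which 1079 were among the 1341 (AURKB adjusted p = 0.0217), and the additive fit passed 1854 (AURKB adjusted p = 0.00971). In the additive fit 2 genes passed in the 5 libraries low in RNA without poly(A) tails, and 143 with FPKM as deposited. Without pRB- control replicate 1 or pRB+ AZD2811 replicate 1 the count was 1. Without pRB- AZD2811 replicate 1, pRB+ control replicate 1 or pRB- control replicate 2 it was 2. Without pRB+ control replicate 2 it was 475, without pRB- AZD2811 replicate 2 it was 994 and without pRB+ AZD2811 replicate 2 it was 1804. With 1 library left out, AURKB passed only in the last 3 of these (adjusted p = 0.0906 without pRB- control replicate 1), while the G2/M median stayed between -0.33 and -0.29.

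AZD2811 in pRB- cells moved few genes past the threshold. Of 12013 genes 0 rose and 4 fell (limma, n = 2 per group), the small RNA genes MIR3940, MIR6884, MIR600 and SNORA32, named after their values were seen and listed at or near 0 under AZD2811; 324 had an unadjusted p under 0.05 against 601 expected by chance. RRM2, a subunit of ribonucleotide reductase, stood at -0.31 ± 0.09 and the mitotic kinase gene TTK at -0.16 ± 0.06, neither past the threshold (adjusted p = 0.992). Camera with its preset correlation called the lists of G1/S (median -0.089), G2/M (-0.062), checkpoint (-0.087), mitochondrial ribosome (-0.090) and sterol genes (-0.16) as lower and histones (2.49) as higher. With an estimated correlation none was called (adjusted p = 0.609 for G1/S, G2/M, sterol genes and histones, 0.588 for the checkpoint and 0.668 for the mitochondrial ribosome), and 0 members of these lists passed over all genes or adjusted over the list alone. The histone value goes with pRB- AZD2811 replicate 1, 1 of the 3 libraries rich in such RNA, and was 0.43 with a term for them, still called with the preset correlation (adjusted p = 5.60e-11) and not with an estimated one (0.573). That term with the preset correlation also ended the call of mitochondrial ribosome genes (median -0.030, camera, adjusted p = 0.452). The G1/S median was then -0.058 and the G2/M median -0.10, and both lists were still called, as were checkpoint and sterol genes. Integrated stress genes (0.18), MYC targets (0.076) and passenger complex genes (-0.10) were called with the term only. None was called with the term and an estimated correlation. The 4 gene calls became 0 without small RNA genes and 143 with FPKM as deposited. Without pRB- control replicate 1 or 2 the count was 15 or 14, without pRB- AZD2811 replicate 1 or 2 it was 14 or 13, without pRB+ control replicate 1 or 2 it was 1, and without pRB+ AZD2811 replicate 1 or 2 it was 2.

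AZD2811 in pRB+ cells gave 0 genes higher and 1 lower (limma, n = 2 per group), SNORD67, named after its values were seen. An unadjusted p under 0.05 was held by 82 genes, against 601 expected by chance. This falls below the number that no effect would give, and the spread within groups includes the difference between library types. Few calls in either pRB state therefore do not show a lack of response to AZD2811. Integrated stress genes had a median of 0.12, 29 of 32 above 0, with the cystine transporter gene SLC7A11 at 0.49 ± 0.15 and CTH at 0.21 ± 0.11, neither past the threshold (adjusted p = 1). G2/M genes had a median of -0.091 with 54 of 60 below 0, PLK1 at -0.18 ± 0.07 (adjusted p = 1). Camera with its preset correlation called G2/M, passenger complex (-0.099) and checkpoint genes (-0.065) as lower, and stress, neuroendocrine (0.062), unfolded protein (0.042) and MYC target genes (0.034) as higher. With an estimated correlation none was called (adjusted p = 0.528, 0.324, 0.324, 0.697, 0.697, 0.697 and 0.954 in that order), and 0 members passed over all genes or adjusted over the list alone. Histones had a median of 0.41 with 39 of 41 above 0, called with the preset correlation only with a library type term (adjusted p = 2.32e-17, and 0.0863 without it; 0.652 with the term and an estimated correlation). Without pRB+ AZD2811 replicate 2 the stress median was -0.063 and the neuroendocrine one -0.033, and without pRB+ control replicate 2 the MYC target median was -0.065. The count of 1 became 79 with FPKM as deposited, 7 and 12 without pRB+ control replicate 1 and 2, 4 and 8 without pRB+ AZD2811 replicate 1 and 2, and 0 without any 1 of the 4 pRB- libraries.

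The difference of the AZD2811 effects between pRB states was tested as an interaction. An unadjusted p under 0.05 was held by 77 genes, against 601 expected by chance. MIR3940 and MIR6884 passed (limma, adjusted p = 0.0496 and 1.46e-06), both seen in the pRB- control libraries and listed at 0 in the 6 others. Those zeros leave the other groups without observed spread, and the sizes moved with the pseudocount. MIR3940 missed the threshold with no filter, a pseudocount of 0.1 or a library type term (adjusted p = 0.161, 0.198 and 0.129) and without any 1 of those 6 libraries (0.0673 to 0.121). For AURKB the interaction was 0.05 ± 0.15 and for RB1 -0.17 ± 0.14 (adjusted p = 1 for both). The count of 2 was between 6 and 15 whichever library was left out (6 without pRB+ AZD2811 replicate 1, 15 without pRB- control replicate 1) and 108 with FPKM as deposited. G2/M genes had a median interaction of -0.011, and 0 of 60 passed over all genes or adjusted over the list alone. Across 12013 genes, which are not independent replicates, the AZD2811 effects in pRB- and pRB+ cells correlated with Pearson r = 0.14 and Spearman rho = 0.313 (covariance 0.0207, no shared library), and 61.5% had the same sign. Of the 4 genes lower in pRB- and the 1 lower in pRB+ cells, 0 were shared. In the additive fit, added after the data had been examined, AZD2811 moved 0 of 12013 genes past the threshold (limma, 4 libraries per arm). There 426 had an unadjusted p under 0.05, against 601 expected by chance. Camera called 10 lists with its preset correlation and none with an estimated one (smallest adjusted p = 0.172), and 143 genes passed with FPKM as deposited.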

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

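The tests of other short RNAs, of scaling, of the 35 splits for pRB and of single libraries for AZD2811 were written before their results were seen; the tests of S phase, of treatment and pRB state as sources of the 3 libraries, of the library type term, of single libraries with that term, of doxycycline and of the splits for AZD2811 were chosen only after. No group of the study held the 4 samples an outlier test needs.

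The interaction between pRB state and AZD2811 passed the threshold for MIR3940 (5.06 on the log2 scale) and MIR6884 (7.85). These are small RNA genes listed at 0 in all but the pRB- control libraries. Their sizes moved with the pseudocount (8.34 and 11.2 with one of 0.1). The zeros leave the other groups without observed spread, so these values do not measure the size of a response. MIR3940 (adjusted p = 0.0496, limma) missed the threshold with no filter, a pseudocount of 0.1 or a library type term (0.161, 0.198 and 0.129) and without any 1 library of the other groups. Camera with its preset correlation also called the interaction for the lists of G1/S genes (median 0.089), unfolded protein genes (0.099), sterol genes (0.15) and histones (-1.95), none of them with an estimated correlation (smallest adjusted p = 0.803) and 1 of them, sterol genes, with a library type term.

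A first pattern is the 3 libraries rich in RNA without poly(A) tails. Against more cells in S phase, the G1/S list had a median of -0.093 in them; against AZD2811, 2 of 4 treated libraries lay above every control library in the histone median; against pRB state, 1 library of a state lay above every library of the other. A library preparation that kept such RNA in 3 libraries may account for it: 26 tested scaRNA and snRNA genes had a median log2 difference of 3.18 with 24 above 0, while 8 histone variant genes with poly(A) tails had one of -0.15. The labels describe 1 preparation for all libraries, and no record of a difference was available.

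A second pattern is the lower cell cycle genes in pRB+ libraries. The tables argue against library type (G2/M median -0.32 with a term for it). The test of scaling decides nothing, since a factor per library moves the list and all genes alike (list median minus that of all genes -0.30 with no scaling). For the number of genes, the real split was the only 1 of the 35 into 4 and 4 libraries to reach its 1619 genes. The fit held the split alone, and the highest other split gave 3. This argues against chance without excluding it, since 35 splits can give no smaller share than 1 of 35. Every other split also mixes pRB+ and pRB- libraries. Doxycycline itself and the RB1 it induces cannot be told apart, since 0 doxycycline libraries lacked the rise of RB1. An effect of pRB on these genes is a hypothesis that stays open beside it.

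Another pattern is the small list shifts with AZD2811, lower G2/M and higher integrated stress genes; the larger shift of histones (1.36 over both states, 0.41 with a library type term) was not weighed. The tables argue against library type as their whole source (medians of -0.10 and 0.15 with a term for it) and against a single library for G2/M genes (at most -0.055 whichever library was left out, and -0.068 with the term). For stress genes a single library stays open: the median was 0.0084 without pRB+ AZD2811 replicate 2 and 0.027 without pRB- AZD2811 replicate 2, though each leaves only a library rich in RNA without poly(A) tails in its group, and stress genes were lower in the 3 such libraries (median -0.25, 1 of 32 above 0). With the term the lowest median was 0.11, without pRB- control replicate 2, while without pRB+ AZD2811 replicate 2 it was 0.13 with a lower quartile of -0.023. For the number of genes the splits cannot exclude chance, since a real count of 0 is reached by all 35 whatever the data; the highest other split, the pRB split, gave 1619, and a small effect of AZD2811 on G2/M genes stays open.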

How the results depend on the processing

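Scaling as deposited, the library type term, the leaving out of small RNA genes, the fits over both states and their alternatives were chosen after seeing the data; the other alternatives were fixed earlier. Counts of genes are given in the order pRB+ against pRB- in control cells, AZD2811 in pRB- cells, AZD2811 in pRB+ cells, pRB+ against pRB- under AZD2811, and the interaction. The causes of the changes were not tested. Leaving out 1 library leaves 1 in a group, which is assumed to vary like the others. The count model alternatives were not run. Depth limits genes near 1 FPKM, where counting error reaches 16.9% for 1500 nucleotides at 1 FPKM as deposited. At 1 scaled FPKM it is larger in libraries with a scaling factor below 1.

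The scaling factors ranged from 0.455 to 0.771 in the 3 libraries rich in RNA without poly(A) tails. In the other 5 they ranged from 1.28 to 1.33, so FPKM as deposited differ in level between library types. With FPKM as deposited the counts were 122, 143, 79, 87 and 108. Over both states they were 143 for pRB and 143 for AZD2811, where 2 of the pRB genes were among the 1341. RB1 was then -0.22 for AZD2811 in pRB- cells, 0.094 for the interaction and -0.17 for AZD2811 over both states, and AURKB -0.45 for pRB over both states (adjusted p = 1, limma). Without small RNA genes the counts were 1, 0, 0, 1 and 0. With no filter they were 7, 2, 0, 1 and 1 (744 for pRB over both states), with a pseudocount of 0.1 7, 4, 0, 2 and 1, and with only the groups compared 9, 1, 0 and 0, where RB1 was 1.96 under AZD2811 (adjusted p = 0.277, limma). With the library type term the interaction count was 1. MIR3940 was lost from the interaction in each setting with a count of 1 (adjusted p 0.129 to 0.198, limma) and kept with FPKM as deposited (5.78e-12). The labels pair the samples by a replicate number only. Deviations of same-numbered libraries correlated between -0.456 and 0.474. With a library type term the range was -0.480 to 0.528, and the largest values turned sign, so they do not settle whether samples were paired. With the replicate block the counts were 6, 2, 0, 1 and 1, and 1631 for pRB over both states. SCRT1 in control cells then missed the threshold (adjusted p = 0.104, limma, and 0.0348 to 0.992 over its alternatives).

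For pRB over both states 10 genes passed with a log2 fold change of at least 1. The robust fit gave 1811 genes, and with the library type term 2163; without small RNA genes it gave 2072, and with both 2455. The type term gave 1530, and 2344 without small RNA genes; leaving these out alone gave 1854. The fit of 4 group means gave 4 and AURKB -0.44 (adjusted p = 0.0516, limma), and 1165 without small RNA genes, and the 5 other libraries gave 2 and AURKB -0.48 (adjusted p = 0.173). For AZD2811 over both states the group means gave 2 genes and the 5 libraries 7, with RB1 -0.024 and AURKB 0.010; RB1 was -0.026 with the type term, alone or with the robust fit or without small RNA genes.

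With an estimated correlation 0 lists were called in each of the 7 comparisons, with or without the type term; with the type term and the preset correlation 1 was called for the interaction. Histones in pRB+ against pRB- control cells turned to -0.22 with the type term under either correlation and to -0.13 without pRB+ control replicate 2 (highest with 1 library left out 3.61). Their interaction turned to 0.34 without pRB- AZD2811 replicate 1 (lowest -4.26). For AZD2811 in pRB+ cells G1/S genes turned to 0.047 without pRB+ control replicate 1 (lowest -0.066) and MYC targets to -0.065 without pRB+ control replicate 2 (highest 0.16). Neuroendocrine and stress genes turned to -0.033 and -0.063 without pRB+ AZD2811 replicate 2 (highest 0.12 and 0.33). For AZD2811 over both states ribosomal proteins turned to 0.0056 without pRB+ AZD2811 replicate 1 (lowest -0.16) and MYC targets to -0.0072 without pRB+ control replicate 2 (highest 0.088). The correlation of AZD2811 effects was 0.305 without small RNAs and histones, -0.842 over the 5 called genes and 0.137 with no filter.

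With each library left out in turn, values ran as follows. For pRB+ against pRB- control cells, 3 to 17 genes passed, RB1 was 2.15 to 2.27, AURKB -0.55 to -0.37 and 9 to 11 lists were called. For AZD2811 in pRB- cells, 1 to 15 genes passed, RB1 was 0.054 to 0.11, AURKB -0.20 to -0.018 and 6 to 8 lists were called. For AZD2811 in pRB+ cells, 0 to 12 genes passed, RB1 was -0.20 to 0.034, AURKB -0.13 to 0.0099 and 6 to 10 lists were called. For pRB under AZD2811, 0 to 14 genes passed, RB1 was 1.94 to 2.13, AURKB -0.49 to -0.34 and 8 to 14 lists were called. For the interaction, 6 to 15 genes passed, RB1 was -0.29 to -0.047, AURKB -0.041 to 0.14 and 2 to 12 lists were called. For pRB over both states, 1 to 1804 genes passed, RB1 was 2.07 to 2.2, AURKB -0.47 to -0.40 and 8 to 11 lists were called. For AZD2811 over both states, 0 to 0 genes passed, RB1 was -0.029 to 0.063, AURKB -0.11 to -0.042 and 6 to 11 lists were called.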

Other observations

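Outside the pRB and AZD2811 comparisons, 102 genes were higher and 8 lower in the 3 libraries rich in RNA without poly(A) tails than in the other 5 (limma with doxycycline and AZD2811 terms), 45 of the higher ones histone genes and 48 small RNA genes. SCARNA7 was higher by 5.20 ± 0.17 and RNU11, an RNA of the minor spliceosome, by 6.69 ± 0.60 on the log2 scale, while SCARNA15 was lower (-3.56 ± 0.25). Lists not yet described follow for the comparison of 4 pRB+ with 4 pRB- libraries, where 643 of all 12013 genes rose and 698 fell. Of 18 Notch and YAP genes 1 was higher and 3 were lower (2 and 4 adjusted over the list alone), of 8 inflammatory genes 2 were lower (1 higher and 4 lower adjusted over the list alone), and of 13 tetraploidy response genes 1 was higher and 2 were lower (1 and 4 adjusted over the list alone). Over all genes and adjusted over the list alone, 1 of 28 mitochondrial ribosome genes was higher and 1 lower, 1 of 13 immediate early genes was lower, and 2 of 33 lysosome and autophagy genes were higher and 3 lower. On either count 0 of 26 glycolysis and hypoxia genes, 0 of 49 ribosomal protein genes and 0 of 21 unfolded protein genes passed (limma).

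The hypotheses here were formed, and their tests chosen, after the list values had been seen. One was that G2/M genes fell by a different amount under AZD2811, and the other that sterol genes, lower in pRB+ cells, returned towards the pRB- level under AZD2811. The median interaction of G2/M genes was -0.011 (quartiles -0.087 and 0.035) with 27 above 0 and 33 below. Its members went both ways, so no shared shift of the list was seen. With 2 libraries per group a small one is not excluded, and differences of single members stay open. The median AZD2811 change of sterol genes in pRB+ cells was -0.0093 with 12 above 0 and 19 below, 0.11 without pRB+ AZD2811 replicate 1 and -0.11 without pRB+ AZD2811 replicate 2. These values argue against a full return over the gap of 0.36 between the control groups. They do not exclude it, since list members are not independent replicates and each group held 2 libraries. With a library type term the pRB difference of the list in control cells was -0.28. A partial return stays open. In pRB- cells the median AZD2811 change of these genes was -0.16, and their pRB difference under AZD2811 was -0.21.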
